A study of Mus musculus with 9 samples.

How the data were processed

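Single-cell RNA sequencing was done on subcutaneous MC38 tumours (a mouse colorectal adenocarcinoma line) grown in C57BL/6J mice. The labels give 9 libraries in 3 groups of 3 mice: untreated, FOLFOX, and FOLFOX+probiotics. Each library was taken as 1 mouse. Replicate numbers follow the order of the samples and pair no mice, and the labels give no batch. Per the labels' protocols, the tumours were digested enzymatically, and libraries were made with a droplet 3' kit and sequenced in paired reads. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq, counted with Cell Ranger on GRCm39, and analysed with Seurat 4.1.0. Per the file headers, the Cell Ranger version was 9.0.1. The deposited matrices hold UMI counts, whole numbers for 55357 features in the barcodes that the authors called as cells. No cell annotation was used here, and all classes were named from the counts. Genes carry the symbols of the deposited feature lists. Gene spans and intron lengths came from GENCODE vM21, joined by gene identifier.

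Barcodes were kept with at least 300 genes, at least 500 UMIs and under 20% of UMIs from mitochondrially encoded genes. Scrublet, as in scanpy 1.11.5, scored doublets in each library with its automatic threshold. In 4 libraries (all 3 FOLFOX libraries and FOLFOX+probiotics replicate 1) it marked under 0.5%, and the top-scoring share of 0.8% per 1000 barcodes was removed instead. Removed shares were 10.97% to 13.92% in those libraries and 1.72% to 10.26% in the other 5. Counts were log-normalised, without integration across libraries. From them 2000 variable genes, 30 principal components and 15 nearest neighbours gave 28 Leiden clusters (igraph, modularity, resolution 1). A cluster took the name of a class when at least 3 of its fixed markers were detected in at least 10% of cells and when its 10 leading genes held no more markers of another class than of its own. Clusters with over 50% called doublets stayed unnamed. Lymphocytes were clustered again with 1500 genes and 20 components into 19 clusters.

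Few fixed markers of malignant cells were detected, namely Cdkn2a, Hmga2 and Tubb3. The tumour compartment was therefore taken as the 11 clusters with under 20 CPM (counts scaled by the total) of both Xist and Ptprc, the pan-leukocyte gene. This definition was chosen after the data were seen. Xist reached at most 8.26 CPM in these clusters and at least 104 CPM in every other cluster. These cells are called Xist-negative cells. That the tumour cells lack Xist is an assumption. Epithelial genes were near 0 in them (Epcam 0.056, Krt8 0.286 and Krt18 0.039 CPM), and the matrix genes Dcn and Col3a1 were detected in 85.5% and 84.9% of them. 5 of the 11 clusters did not pass the naming rule with the fixed malignant markers, 2 of them for a leading marker of NK cells or of fibroblasts, and an alternative left all 5 out.

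UMI counts were summed per library within a class and over all kept cells. Genes were tested with edgeR 4.0.16 (filterByExpr, TMM, robust quasi-likelihood fit of all 9 libraries, R 4.3.3), with Benjamini-Hochberg adjustment within class and comparison and a threshold of 0.05. The classes tested were Xist-negative cells, mononuclear phagocyte-like cells and T cell-like cells, since no other class had the planned 50 cells in every library. Cell numbers per class were tested with the same edgeR model, with the number of kept cells as library size and adjustment over 8 classes. A two-sided exact permutation test of the 3 against 3 shares stands beside it, and 0.1 is the smallest p that this design allows. 30 gene lists and 19 lists of cell type markers were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted within class and comparison. Camera with an estimated correlation and fry were run beside it. A list value per library is the median over its members of log2 CPM minus the gene's mean over the 9 libraries. The errors of log2 fold changes are standard errors of the edgeR fit.

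The comparisons, tests, filters, gene lists, marker lists and the rule for naming genes were fixed before the data were examined. By that rule the named genes were those with adjusted p under 0.05, libraries of the 2 groups that do not overlap and a mean log2 CPM of at least 5. Gm and Rik gene models, pseudogenes, mitochondrially encoded genes and ribosomal protein genes were left out. The 5 largest changes in each direction were taken in Xist-negative cells, and 3 in each direction in the other classes and over all cells. Where no gene passed, the 2 genes above 0 and the 2 below 0 with the smallest p were given as values. Of each list described, up to 4 members with the smallest p were named.

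Alternatives planned before were DESeq2 1.42.0, no scaling factors, no filter on low counts, stricter cell filters (500 genes, 1000 UMIs, 10% mitochondrial), doublets kept, TMM scaling of cell numbers, shares of immune cells, a higher clustering resolution (1.5, which gave 34 clusters), only the 6 libraries compared, an estimated correlation, and leaving out each library in turn. Alternatives chosen after the data were seen were 1 doublet rule for all libraries, cells with at least 2000 UMIs, only the clusters that passed the naming rule, a ratio from UMIs of marker genes, a term for 2 untreated libraries that stand apart, and list tests without a set of 30 genes. The term leaves untreated replicate 1 as the lone untreated library, assumed to vary like the other groups. The set holds genes that were over 1 log2 unit lower in untreated replicate 3 than in untreated replicate 2 in each of the 3 classes.

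The gene test was tested on simulated data with the sizes and spread of these libraries. It called 49% of 100 genes changed by a log2 size of 1 and 95% of 100 genes changed by a log2 size of 2. Another 14 calls, 8.86% of all calls, were genes that had not been changed. No gene was called between the simulated FOLFOX+probiotics and untreated groups, between which no gene was changed. The simulation held no libraries that stand apart, as 2 untreated libraries do in the real data. DESeq2 called 84% of the changed genes. Camera called 2 of 2 changed lists and 0 of 40 unchanged lists. Simulated genes were drawn independently, so this cannot tell how camera with the preset correlation treats correlated genes. In the real data every list call was lost with an estimated correlation. The test of shares called 1 class changed 3-fold and 0 of 7 others. Total counts per library lay between 146620002 and 183740858 UMIs. Wilson 95% intervals of shares cover counting error only.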

Results

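Tumours of 9 mice were profiled by droplet single-cell RNA sequencing, 3 in each of 3 groups. All mice carried subcutaneous MC38 tumours, a transplanted mouse colorectal adenocarcinoma line. One group was left untreated, one received FOLFOX, a chemotherapy of a fluoropyrimidine, folinic acid and a platinum drug, and one received FOLFOX and a probiotic consortium by mouth. Dosing with probiotics began 1 week after inoculation, and chemotherapy began at 2 weeks. The libraries held 11910 to 17402 barcodes and 146620002 to 183740858 UMIs, with a median of 5090 to 10123 UMIs per kept cell. Of 128943 cells that passed the filters, 117707 were kept after doublet removal, 11008 to 14844 per library.

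Most cells were Xist-negative or mononuclear phagocyte-like cells. Xist-negative cells, taken as the tumour compartment though epithelial genes were near 0 in them (Epcam 0.056 and Krt8 0.286 CPM), made up 52.8% ± 11 of untreated cells (SD, n = 3), 73.6% ± 7.39 of FOLFOX cells and 62.5% ± 5.14 of FOLFOX+probiotics cells. Mononuclear phagocyte-like cells made up 33.3% ± 10.3, 20.6% ± 5.71 and 23.5% ± 5.84 in the same order. T cell-like cells followed with 5.54% ± 0.657, 3.19% ± 1.88 and 9.89% ± 5.00. Dendritic, NK, fibroblast, mural and endothelial cell-like classes each held under 2% of the cells of a group on average. Gene tests rest on 6317 to 11159 Xist-negative, 1979 to 6445 mononuclear phagocyte-like and 247 to 1721 T cell-like cells per library.

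**Figure D1:**
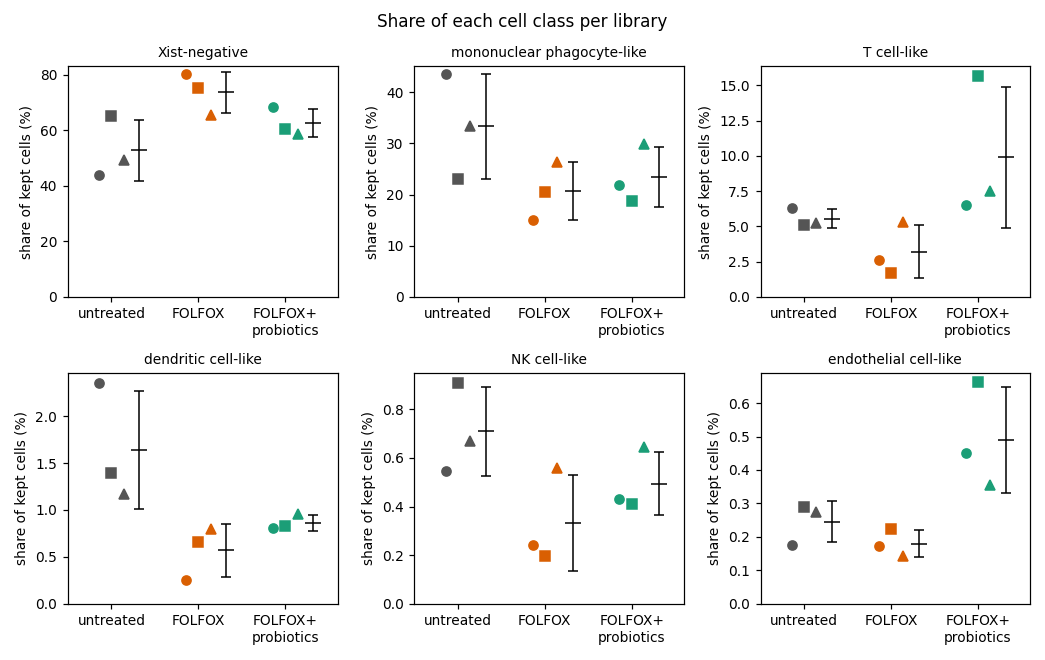
Share of kept cells in 6 cell classes (y axis, percent) for each library (points; circle, square and triangle for replicates 1, 2 and 3), with the mean and SD of each group of 3. T cell-like shares of the FOLFOX+probiotics libraries lie between 6.53% and 15.6%, above all 3 FOLFOX libraries.

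Untreated replicates 2 and 3 stood apart from the other 7 libraries in every class tested. Genes spanning over 50 kb took 12.8% and 12.9% of their UMIs, and 20.4% to 21.5% in the other libraries (Wilson 95% intervals at most 0.013 points wide). The same held within Xist-negative cells (12.7% and 12.5% against 19.7% to 20.5%), mononuclear phagocyte-like cells (13.4% and 13.6% against 23.2% to 25.1%) and T cell-like cells (14.4% and 14.3% against 25.1% to 29.4%). Comparisons with untreated tumours are thus partly confounded with this library difference, and untreated replicate 1 is the only untreated library of the other kind. Those comparisons are given again with a model term for the 2 libraries, called the library term. It sets 3 libraries against untreated replicate 1 alone, which is assumed to vary like the other groups, so its values lend no independent support. A further 30 genes, such as Cox5a, Cyc1, Ier2 and Junb, were over 1 log2 unit lower in untreated replicate 3 than in untreated replicate 2 in each of the 3 classes. This set was found after the data were seen. Its median log2 fold change between FOLFOX+probiotics and FOLFOX was -1.29, -1.19 and -1.41 in Xist-negative, mononuclear phagocyte-like and T cell-like cells, with 29, 30 and 30 of 30 genes below 0 and 0 called.

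**Figure D2:**
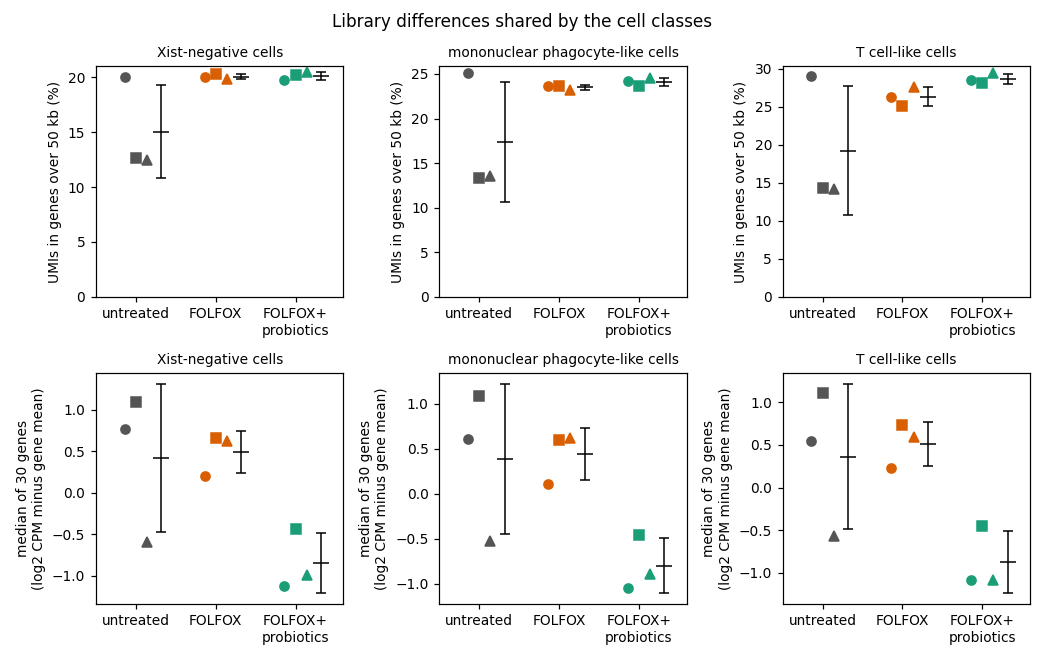
Share of UMIs in genes over 50 kb (top, percent) and median of the 30 genes (bottom, log2 CPM minus the gene mean over 9 libraries) per library in 3 classes, with the mean and SD of each group of 3. Untreated replicates 2 and 3 lie below 15% at the top, and untreated replicate 3 lies with the FOLFOX+probiotics libraries below 0 at the bottom.

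The comparison of FOLFOX with untreated tumours asks what the chemotherapy alone did. In Xist-negative cells Nr4a3, an orphan nuclear receptor gene, rose by 2.18 log2 units (SE 0.35, n = 3 against 3, edgeR adjusted p = 0.0197), from 4.09 ± 0.61 to 6.34 ± 0.26 log2 CPM. Homer1, a postsynaptic scaffold gene, rose by 1.78 (SE 0.22, adjusted p = 0.015), Trim69, an E3 ubiquitin ligase gene, by 1.68 and Lsmem1 by 1.54. Cd74, the invariant chain of MHC class II, fell by 1.36 (SE 0.34, adjusted p = 0.04), the aminoacylase gene Acy1 fell by 1.33, Fdps, an enzyme of isoprenoid and cholesterol synthesis, fell by 1.26 (SE 0.20, adjusted p = 0.0197), and the thioredoxin gene Txn1 fell by 1.16. C1qb, a complement gene that is a marker of mononuclear phagocytes, fell by 1.22. For each of these genes all 3 FOLFOX libraries lay on one side of all 3 untreated libraries, as the naming rule required.

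The clusters of Xist-negative cells differ between libraries too: 1 held 38.1% and 26.8% of the cells of untreated replicates 2 and 3 (4896 and 3434 cells) and 0.264% to 3.58% elsewhere. Of 22246 genes tested in Xist-negative cells, 994 rose and 824 fell, or 1702 and 114 without scaling factors, where the median of all genes lies 0.32 log2 units higher. DESeq2 called 3665 genes. With the library term 1818 of the 1818 genes kept their direction, which their selection on these same libraries favours. The median ratio of their log2 fold changes, with the term over without, was 0.782. The count of called genes was 1 without untreated replicate 3, 18 without untreated replicate 2, 2 without FOLFOX replicate 2, 2 without FOLFOX replicate 3, 1077 without FOLFOX replicate 1 and 7178 without untreated replicate 1. No gene was called by edgeR in a fit of only the 6 libraries compared (5523 with an unadjusted p under 0.05) or when the clusters that did not pass the naming rule were left out (3551).

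In Xist-negative cells 13 of 47 lists were called, and 9 of the 13 had per-library medians that did not overlap between the groups, where chance gives 10% for a list not chosen, as these were, on the same libraries. Cholesterol synthesis genes fell, with 16 of 16 below 0, a median of -0.49 and all 3 FOLFOX libraries below the untreated ones (camera adjusted p = 3.78e-05, and adjusted p = 0.666 with an estimated correlation). 6 members were called and 8 when adjusted over the list alone, among them Fdps, Mvd (-0.98), Nsdhl (-0.94) and Fdft1 (-0.80), which all encode enzymes of the pathway. Without scaling factors the median was -0.23 with 12 of 16 below 0, and with the library term it was -0.81. Nuclear genes of oxidative phosphorylation fell too, with 18 of 19 below 0, a median of -0.63 and all 3 FOLFOX libraries below the untreated ones (adjusted p = 4.47e-06, and adjusted p = 0.603 with an estimated correlation). 8 were called and 15 adjusted over the list alone, such as Ndufv1 (-0.71), Uqcrc1 (-0.63) and Ndufa4 (-0.82), and the library term gave a median of -0.26. Without scaling factors the median was -0.33.

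MHC class II genes fell in Xist-negative cells, with 11 of 12 below 0, a median of -0.90 and all 3 FOLFOX libraries below the untreated ones (camera adjusted p = 4.25e-05, and adjusted p = 0.603 with an estimated correlation). 6 were called and 10 adjusted over the list alone, including H2-Oa (-1.21), H2-Ab1 (-1.51), Cd74 and H2-Aa (-1.58), and the library term gave a median of -1.14. Without scaling factors the median was -0.63 for this list, -0.34 for the next and -0.20 for MHC class I. Markers of mononuclear phagocytes fell in the same cells, with 19 of 24 below 0, a median of -0.64 and all 3 FOLFOX libraries below the untreated ones (adjusted p = 0.000507, and adjusted p = 0.666 with an estimated correlation). Of these markers 5 were called and 7 adjusted over the list alone, C1qb, C1qa (-1.11), C1qc (-1.17) and Ms4a7 (-1.18) among them, and the library term gave a median of -0.36. Mononuclear phagocyte-like cells made up 33.3% of untreated and 20.6% of FOLFOX cells. Doublet removal took 2.98% to 10.26% of cells in untreated and 12.58% to 13.92% in FOLFOX libraries. RNA carried from phagocytes, or doublets with them, was thus not separated from a change within Xist-negative cells. MHC class I genes, which carry peptides to CD8 T cells, had a median of -0.51 and all 3 FOLFOX libraries below the untreated ones (adjusted p = 0.000433, and adjusted p = 0.666 with an estimated correlation). 2 of 15, Psmb10 (-0.74) and H2-K1 (-0.74), were called lower, 9 were lower and 1 higher adjusted over the list alone, and the library term gave a median of -0.09.

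Cell cycle genes were lower in Xist-negative cells of FOLFOX tumours. These cells had a median of 9417 to 12082 UMIs in FOLFOX and 13905 to 16848 in untreated libraries. Depth and the larger share of removed doublets in FOLFOX were not separated from this difference. Of 24 mitotic genes 22 lay below 0 with a median of -0.23 and all 3 FOLFOX libraries below the untreated ones (camera adjusted p = 0.000557, and adjusted p = 0.603 with an estimated correlation), though without scaling factors the median was 0.05. 5 were called and 10 adjusted over the list alone, among them Cdc20 (-0.79), the Aurora kinase gene Aurkb (-0.98), Cenpa (-0.75) and the survivin gene Birc5 (-0.91), and the library term gave a median of -0.20. Of 20 S phase genes 19 lay below 0 with a median of -0.34 and all 3 FOLFOX libraries below the untreated ones (adjusted p = 0.000433, and adjusted p = 0.666 with an estimated correlation), though without scaling factors 11 lay below 0 and 9 above, with a median of -0.04. 3 were called (Chaf1b -0.76, Rrm2 -0.66 and Cdc45 -0.73) and 6 adjusted over the list alone, and the library term gave a median of -0.10. Genes of fluoropyrimidine and folate handling had a median of -0.30, or 0.00 without scaling factors, with 15 of 19 below 0 and 2 FOLFOX libraries below all untreated ones (adjusted p = 0.0146, and adjusted p = 0.666 with an estimated correlation). Thymidylate synthase Tyms (-0.93), the target of fluoropyrimidines, and thymidine kinase Tk1 (-0.91) were called, 8 were lower and 1 higher adjusted over the list alone, adjusted p = 0.0623 without untreated replicate 2, and the library term gave a median of -0.14. Targets of p53 gave a median of -0.20 with 16 of 23 below 0 and were not called (adjusted p = 0.157).

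In mononuclear phagocyte-like cells of FOLFOX tumours, p53 targets rose and mitotic genes fell. Of 23 p53 targets 16 lay above 0 with a median of 0.22 and all 3 FOLFOX libraries above the untreated ones (camera adjusted p = 0.0301, and adjusted p = 0.972 with an estimated correlation). 4 were called and 5 adjusted over the list alone: Phlda3 rose by 1.81, Trp53inp1 by 1.30, Mdm2, the ligase that degrades p53, by 1.19, and the cyclin gene Ccng1 by 1.18. All 24 mitotic genes lay below 0 with a median of -0.61 and all 3 FOLFOX libraries below the untreated ones (adjusted p = 4.8e-08, and adjusted p = 0.972 with an estimated correlation). Of these 5 were called and 9 adjusted over the list alone, Aurkb (-1.18), Cdk1 (-0.95), Birc5 (-1.34) and Ube2c (-1.08) among them. With the library term the medians were 0.58 and -0.81. The p53 call ended without untreated replicate 1 (adjusted p = 0.452) or FOLFOX replicate 1 (adjusted p = 0.115).

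Single genes of the mononuclear phagocyte-like cells changed as well, in a class whose clusters differ between libraries. Of all kept cells, 1 of its clusters held 19.4% and 29.0% in untreated replicates 2 and 3 (2500 and 3719 cells) and 1.04% to 5.50% elsewhere, and another held 24.4% in untreated replicate 1 (3605 cells) and 0.171% to 4.77% elsewhere. Astl, an astacin-like protease gene, rose by 2.25 (SE 0.46, n = 3 against 3, edgeR adjusted p = 0.031), Plekhg2 by 2.24 (SE 0.35, adjusted p = 0.0118) and Trim69 by 1.81 (SE 0.20, adjusted p = 0.00293). The transmembrane genes Tmem176b and Tmem176a fell by 1.38 each, the latter a marker of gamma-delta T cells. Birc5, a marker of cycling lymphocytes, fell by 1.34. Each had non-overlapping libraries, as the naming rule required. Cholesterol synthesis genes fell, with 16 of 16 below 0, a median of -0.53 and all 3 FOLFOX libraries below the untreated ones (camera adjusted p = 0.000915, and adjusted p = 0.972 with an estimated correlation). Fdps (-1.35) was the 1 member called and the 1 adjusted over the list alone. The call ended without untreated replicate 1 (adjusted p = 0.146), with which alone the library term compares (median -0.95). Among 16016 genes 373 rose and 47 fell, and DESeq2 called 1087. With the library term 420 of the 420 genes kept their direction, with a median ratio of log2 fold changes of 0.913. Selection of these genes on the same libraries favours a kept direction. The count of called genes was 61 without untreated replicate 3, 78 and 83 without FOLFOX replicates 2 and 3, 139 without untreated replicate 2, 5467 without untreated replicate 1 and 215 with only the 6 libraries compared.

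**Figure D3:**
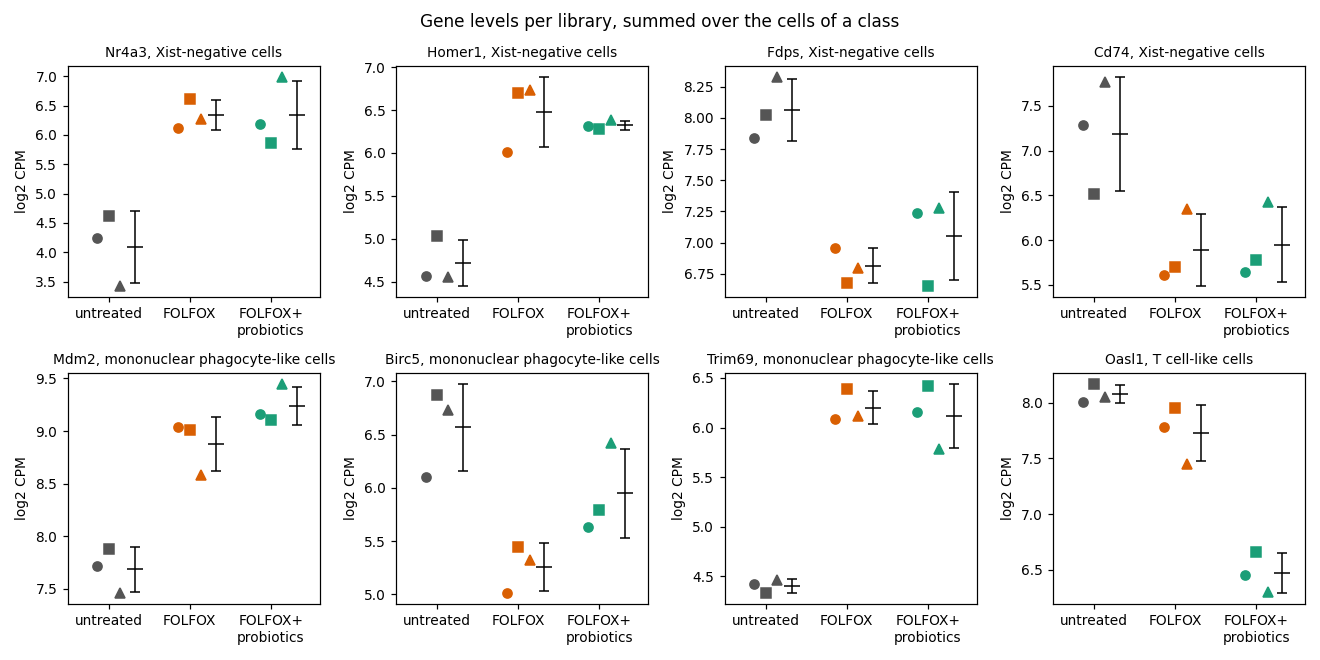
Level of 8 named genes (y axis, log2 CPM) summed over the cells of a class in each library, with the mean and SD of each group of 3. Nr4a3 and Homer1 are higher and Fdps and Cd74 lower in all 3 FOLFOX libraries than in the untreated libraries, and Oasl1 in T cell-like cells is lowest in the FOLFOX+probiotics libraries, at 6.47 ± 0.18.

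In T cell-like cells of FOLFOX tumours MHC class II genes and markers of several cell types, T cells included, were lower. Their clusters differ between libraries too: 1 held 389 and 390 cells in untreated replicates 2 and 3 and 17 to 45 elsewhere, and another held 12 and 7 there and 125 to 853 elsewhere. MHC class II genes fell there, with 11 of 11 below 0, a median of -1.60 and all 3 FOLFOX libraries below the untreated ones (camera adjusted p = 1.69e-07, and adjusted p = 0.376 with an estimated correlation). No member was called and 10 were adjusted over the list alone, such as H2-Aa (-1.89) and H2-DMa (-1.47), and the library term gave a median of -0.90. Markers of B cells, such as the heavy chain gene Ighm (-1.50), fell with 8 of 8 below 0, a median of -1.63 and 4 adjusted over the list alone (adjusted p = 7.47e-05, and adjusted p = 0.374 with an estimated correlation), again with all 3 FOLFOX libraries lower, and the library term gave a median of -0.50. B cells sit among the lymphocytes, where an unnamed cluster of 82 cells was led by Bank1, and another of 34 by Igkc. Larger unnamed clusters held 473 cells led by mt-Rnr2 and 350 led by Il1b, Lyz2 and C1qa, 62% of the latter called doublets. A further 137 unnamed cells were led by Gzmd, with 61.31% called doublets. These cluster sizes precede doublet removal. Unnamed lymphocytes of every kind made up 0.951% ± 0.507 of untreated and 0.188% ± 0.0546 of FOLFOX cells, so these are not shares of B cells. Markers of mononuclear phagocytes had a median of -1.0 with 21 of 24 below 0 and 2 FOLFOX libraries below all untreated ones (adjusted p = 7.53e-05, and adjusted p = 0.505 with an estimated correlation). None of these markers passed adjusted over the list alone, and the library term gave a median of -0.25. For these markers and the MHC class II genes, RNA carried from phagocytes, or doublets with them, was not separated from a change within T cell-like cells. Neutrophil markers (median -1.45, 6 of 6 below 0, adjusted p = 0.000264), plasma cell markers (-11.36, 5 of 5, adjusted p = 0.00236) and markers of T cells themselves (-0.43, 19 of 21, adjusted p = 0.00528) were called lower too (adjusted p = 0.374 each with an estimated correlation), the last 2 not without untreated replicate 1 (adjusted p = 0.16 and 0.0603). The library term gave medians of -0.62, -7.81 and -0.18 in that order. Without scaling factors the T cell markers had a median of -0.24 with 15 of 21 below 0. T cell-like cells had 1 gene called by edgeR of 11174 tested, Trim69, which rose by 2.40 (SE 0.31, adjusted p = 0.0446) in all 3 libraries and which lay outside the naming rule and was chosen after its values were seen. An unadjusted p under 0.05 was reached by 1673 genes, DESeq2 called 82, and the count was 3961 without untreated replicate 1 and 0 without any 1 of the other 5 libraries or with only the 6 libraries compared. By the naming rule, Rhoq (1.64) and the motor gene Myo10 (1.48) had the smallest p above 0, and Zfp36 (-1.51), which promotes mRNA decay, and the chemokine receptor gene Cxcr3 (-1.66) below 0 (adjusted p = 0.125 to 0.172, non-overlapping libraries).

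Over all cells of FOLFOX tumours Trim69 rose by 1.64 (SE 0.28, n = 3 against 3, edgeR adjusted p = 0.0423) and Homer1 by 1.60. Fdps fell by 1.2, Sh3bgrl3 fell by 1.13 and the cold-inducible gene Rbm3 fell by 1.13. Each had non-overlapping libraries, as the naming rule required. Among 24051 genes 228 rose and 14 fell, or 827 and 18 without scaling factors, and DESeq2 called 2483. With the library term 242 of the 242 genes kept their direction, with a median ratio of log2 fold changes of 0.991. Selection on the same libraries favours a kept direction here too. The count of called genes was 3 without any 1 of untreated replicates 2 and 3 and FOLFOX replicates 2 and 3, 421 without FOLFOX replicate 1, 6727 without untreated replicate 1 and 3 with only the 6 libraries compared. No class share passed the test in this comparison: dendritic cell-like cells, which prime T cells, made up 1.64% ± 0.628 of untreated and 0.571% ± 0.282 of FOLFOX cells (log2 difference -1.52, SE 0.45, adjusted p = 0.0636, all 3 FOLFOX libraries lower, exact permutation p = 0.1). Without FOLFOX replicate 3, dendritic, NK and T cell-like shares were called lower (adjusted p = 0.0249, 0.0162 and 0.0475). The immune share of cells was 41.2% ± 11.2 in untreated and 24.7% ± 7.6 in FOLFOX tumours (exact permutation p = 0.2).

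The comparison of FOLFOX+probiotics with FOLFOX asks what the probiotics added to chemotherapy. T cell-like cells rose from 3.19% ± 1.88 to 9.89% ± 5.00 of cells (log2 difference 1.63, SE 0.49, n = 3 against 3, edgeR adjusted p = 0.037, exact permutation p = 0.1). Endothelial cell-like cells, which line vessels, rose from 0.180% ± 0.0401 to 0.489% ± 0.158 (log2 difference 1.44, SE 0.35, adjusted p = 0.0225, exact permutation p = 0.1). In both classes all 3 FOLFOX+probiotics libraries lay above all 3 FOLFOX libraries. The T cell-like call ended without FOLFOX+probiotics replicate 2 (1.14, adjusted p = 0.168), FOLFOX replicate 1 (adjusted p = 0.0718) or FOLFOX replicate 2 (adjusted p = 0.116), and the endothelial call ended without FOLFOX replicate 1 (1.42, adjusted p = 0.0695) or FOLFOX+probiotics replicate 2 (1.16, adjusted p = 0.101). With the same doublet rule in every library adjusted p was 0.0781 for T cell-like and 0.283 for endothelial cells. It was 0.0707 for both with at least 2000 UMIs per cell and 0.147 for both with TMM scaling, so that each of these ends both calls. Barcodes start at 2019 and 1289 UMIs in FOLFOX replicates 2 and 3 and at 500 or 501 in the other libraries, while T cell-like cells have a median of 1609 to 3329 UMIs per library. No other class passed.

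CD8 T-like cells made up 1.60% ± 0.924 of FOLFOX and 4.61% ± 3.06 of FOLFOX+probiotics cells, and regulatory T-like cells 0.407% ± 0.285 and 0.830% ± 0.130. The latter include a cluster of 123 cells named by Icos, Ikzf2 and Il2ra. Foxp3 was not among its markers that passed, which limits this share and the ratio below. CD4 conventional T-like cells made up 0.517% ± 0.494 and 2.66% ± 0.959, with all 3 FOLFOX+probiotics libraries above the FOLFOX ones, and gamma-delta T-like cells 0.0367% ± 0.0449 and 0.158% ± 0.0747. These shares were not tested. The log2 ratio of CD8 T-like to regulatory T-like cells was 2.01 ± 0.36 and 2.29 ± 0.87, a difference within the spread of replicates (exact permutation p = 0.8) whose sign turned without FOLFOX+probiotics replicate 2 (-0.21). The immune share was 24.7% ± 7.6 and 34.7% ± 4.8 (exact permutation p = 0.2). Over all cells, markers of T cells rose, with 21 of 21 above 0 and a median of 1.03 (camera adjusted p = 1.64e-11, and adjusted p = 0.462 with an estimated correlation). No member passed over all genes or adjusted over the list alone, Lat (1.22), Cd28 (1.34), Cd2 (1.16) and Trbc2 (1.23) had the smallest p, and 1 FOLFOX+probiotics library lay above all FOLFOX libraries. Endothelial markers rose too, with 12 of 15 above 0, a median of 0.78 and 2 libraries above all FOLFOX libraries (adjusted p = 3.24e-06, and adjusted p = 0.462 with an estimated correlation). Emcn (1.52), Ptprb (1.54) and Ccl21a were the 3 that passed adjusted over the list alone, and none passed over all genes.

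Type I interferon response genes fell with probiotics in all 3 classes. In Xist-negative cells 21 of 21 lay below 0 with a median of -0.88 (camera adjusted p = 6.43e-09, and adjusted p = 0.922 with an estimated correlation). In mononuclear phagocyte-like cells the median was -0.84 with 21 of 21 below 0 (adjusted p = 7.33e-12, and adjusted p = 0.955 with an estimated correlation), and in T cell-like cells it was -0.84 with 20 of 21 below 0 (adjusted p = 1.14e-13, and adjusted p = 0.571 with an estimated correlation). In each class all 3 FOLFOX+probiotics libraries lay below all 3 FOLFOX libraries, and leaving out any 1 of the 6 libraries kept the call. Members of the list did not pass over all genes, and 6, 9 and 10 passed adjusted over the list alone. In Xist-negative cells the nucleotide kinase Cmpk2 (-1.64), the oligoadenylate synthetases Oas2 (-1.68) and Oasl1 (-0.98) and the antiviral GTPase Mx1 (-1.76) had the smallest p. In mononuclear phagocyte-like cells these were Oas2 (-1.32), Ifi44 (-1.51), Mx1 (-1.04) and Cmpk2 (-1.10), and in T cell-like cells Oasl1 (-1.27), Cmpk2 (-1.39), Mx1 (-1.17) and Xaf1 (-1.09). Untreated replicate 1 lay at -0.59 and untreated replicates 2 and 3 at 0.52 and 0.64 in Xist-negative cells, against a mean of 0.34 ± 0.22 for FOLFOX and -0.65 ± 0.64 for FOLFOX+probiotics. From untreated replicate 2 to 3, where the set of 30 genes steps down by over 1 log2 unit, the list steps by 0.14, 0.19 and 0.24 in the 3 classes. Mitochondrially encoded genes fell in the same comparison, with medians of -0.25, -0.31 and -0.43 and 12 of 13, 13 of 13 and 11 of 11 below 0 (adjusted p = 0.0201, 0.00545 and 0.0172, and adjusted p = 0.922, 0.955 and 0.676 with an estimated correlation), and these calls ended without FOLFOX replicate 3 (adjusted p = 0.133, 0.0742 and 0.105). The call in Xist-negative cells also ended without FOLFOX+probiotics replicate 1 (camera adjusted p = 0.0958).

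**Figure D4:**
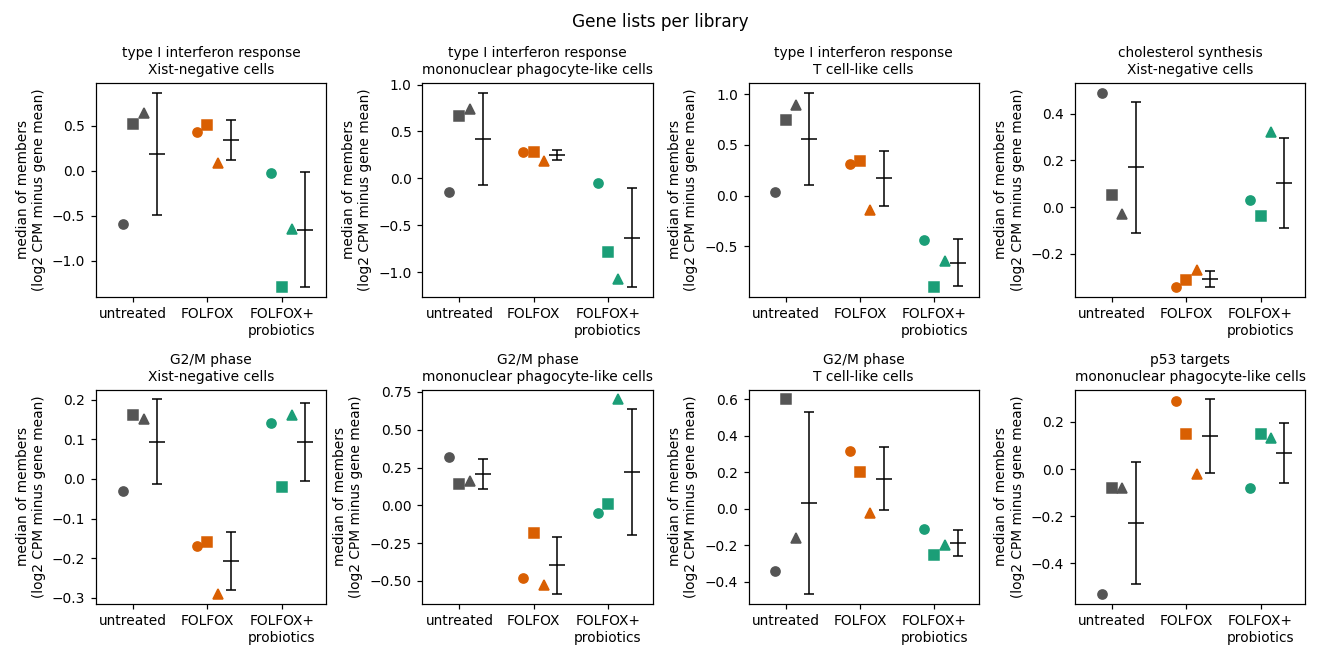
Median over the members of 4 gene lists (y axis, log2 CPM minus the gene mean over 9 libraries) per library in the named classes, with the mean and SD of each group of 3. The interferon list is lower in all 3 FOLFOX+probiotics libraries than in the FOLFOX libraries in each class, and mitotic genes in Xist-negative cells are lowest in FOLFOX, at -0.21 ± 0.07, where without scaling factors their median difference from untreated is 0.05.

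Mitotic genes rose with probiotics in Xist-negative and mononuclear phagocyte-like cells and fell in T cell-like cells. In Xist-negative cells 23 of 24 lay above 0 with a median of 0.34 (camera adjusted p = 9.49e-08, and adjusted p = 0.576 with an estimated correlation), in mononuclear phagocyte-like cells 24 of 24 with a median of 0.64 (adjusted p = 6.16e-15, and adjusted p = 0.955 with an estimated correlation). The former had 8 and the latter 13 members that passed adjusted over the list alone, such as Kif20a (0.55 and 1.10) and Plk1 (0.54 and 0.84), and 0 over all genes. In T cell-like cells 22 of 24 lay below 0 with a median of -0.31, and Ccna2 (-1.09) was the 1 member that passed adjusted over the list alone (adjusted p = 0.000455, and adjusted p = 0.571 with an estimated correlation). In each class the 3 libraries of the 2 groups did not overlap, and the difference between classes was not tested. The T cell-like clusters differ between these groups as well: 1 held 92 of 347, 50 of 247 and 229 of 778 cells in FOLFOX and 323 of 740, 734 of 1721 and 456 of 912 in FOLFOX+probiotics libraries. Cycling lymphocyte-like cells made up 0.459% ± 0.154 and 0.718% ± 0.403 of all cells, so a change of T cell mix was not separated here either. S phase genes rose in Xist-negative cells, with 18 of 20 above 0, a median of 0.36 and 2 libraries above all FOLFOX libraries (adjusted p = 9.95e-06, and adjusted p = 0.922 with an estimated correlation). Rrm2 (0.92), a subunit of ribonucleotide reductase, Chaf1b (0.51) and Mcm4 (0.51) passed adjusted over the list alone. Xist-negative cells had a median of 9417 to 12082 UMIs in FOLFOX and 14913 to 16622.5 in FOLFOX+probiotics libraries. In the same order, mononuclear phagocyte-like cells had 4329.5 to 5250 and 5974 to 7916. T cell-like cells, whose mitotic genes fell, had 2775 to 3329 and 2310.5 to 2545. Doublet removal took 12.58% to 13.92% of cells in FOLFOX and 1.72% to 10.97% in FOLFOX+probiotics libraries. Neither depth nor doublet removal was separated from the differences in mitotic and S phase genes.

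Cholesterol synthesis genes rose with probiotics in Xist-negative cells, with 14 of 16 above 0, a median of 0.41 and all 3 libraries above the FOLFOX libraries (camera adjusted p = 9.95e-06, and adjusted p = 0.922 with an estimated correlation). No member passed adjusted over the list alone, and Fdft1 (0.56) and Nsdhl (0.57) had the smallest p. Genes of dissociation and the immediate early response fell there, with 12 of 15 below 0, a median of -0.64 and all 3 libraries below the FOLFOX libraries (adjusted p = 0.00297, and adjusted p = 0.922 with an estimated correlation). 7 passed adjusted over the list alone, among them the heat shock gene Hspa1b (-0.95), Atf3 (-1.04), Ier2 (-2.25) and Jun (-1.38). Ier2 and Junb of this list are in the set of 30 genes, and without the set adjusted p was 0.0239. For oxidative phosphorylation in Xist-negative cells the median was 0.26 and the mean -0.05 while the test called the list higher, with 13 of 19 above 0 and all 3 libraries above the FOLFOX libraries (adjusted p = 0.0201, and adjusted p = 0.922 with an estimated correlation). Of its members 5 were higher and 2 lower adjusted over the list alone, Cox5a (-2.54) and Cyc1 (-1.64) are in the set of 30 genes, adjusted p was 0.000443 without that set, and adjusted p was 0.0778 without FOLFOX replicate 1.

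In T cell-like cells of FOLFOX+probiotics tumours the list of naive and memory genes rose, with 10 of 14 above 0, a median of 0.54 and all 3 libraries above the FOLFOX libraries (camera adjusted p = 0.0172, and adjusted p = 0.571 with an estimated correlation). No member passed adjusted over the list alone, and the transcription factor genes Tcf7 (1.17) and Lef1 (0.80), the lymph node homing receptor Ccr7 (1.04) and Dapl1 (-1.40) had the smallest p. Tcf7 and Lef1 also lead the cluster of CD4 conventional T-like cells, whose untested share was higher in all 3 libraries, so a change of T cell mix was not separated from a change within cells. Markers of B cells (median 0.67, 7 of 8 above 0, adjusted p = 0.0149), plasma cells (8.72, 4 of 5, adjusted p = 0.0149) and neutrophils (0.65, 5 of 6, adjusted p = 0.0175) were called higher in the same class (adjusted p = 0.571 each with an estimated correlation). The B cell call ended without FOLFOX replicate 2 or FOLFOX+probiotics replicate 1 or 3 (adjusted p = 0.0655, 0.165 and 0.122), the plasma cell call without FOLFOX+probiotics replicate 2 (0.0538), and the neutrophil call without FOLFOX replicate 1 or 3 or FOLFOX+probiotics replicate 2 (0.187, 0.178 and 0.0755). The naive and memory call ended without FOLFOX replicate 1 (adjusted p = 0.319) or FOLFOX+probiotics replicate 3 (adjusted p = 0.206). DNA repair genes fell, with 17 of 22 below 0, a median of -0.30 and all 3 libraries below the FOLFOX libraries (adjusted p = 0.00577, and adjusted p = 0.571 with an estimated correlation), and the histone gene H2ax (-2.37) passed adjusted over the list alone. In mononuclear phagocyte-like cells markers of neutrophils rose, with 13 of 15 above 0, a median of 0.59 and 2 libraries above all FOLFOX libraries (adjusted p = 0.00473, and adjusted p = 0.955 with an estimated correlation). Lcn2 (2.49) alone passed adjusted over the list alone, and adjusted p was 0.0942 without FOLFOX replicate 1.

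No single gene passed edgeR's test between FOLFOX+probiotics and FOLFOX in Xist-negative, mononuclear phagocyte-like or T cell-like cells or over all cells. An unadjusted p under 0.05 was reached by 2833, 1633, 806 and 2582 genes, and DESeq2 called 512, 180, 97 and 518. Without FOLFOX replicate 1 edgeR called 112, 27, 24 and 29 genes, and with only the 6 libraries of the 2 groups 173, 47, 167 and 175. By the naming rule, the smallest p among genes above 0 in Xist-negative cells were those of Rbm3 (1.22, SE 0.18, adjusted p = 0.122) and Rrm2, a marker of cycling lymphocytes (0.92, adjusted p = 0.176). Among genes below 0 they were those of the growth factor gene Pdgfa (-1.01, adjusted p = 0.181) and Pdcd5 (-1.36, adjusted p = 0.193). Mononuclear phagocyte-like cells had Rbm3 (1.53), the adhesion gene Vcam1 (1.38), the heat shock gene Hsph1 (-1.39) and Swt1 (-1.07), all at adjusted p = 0.169. T cell-like cells had Ramp3 (1.56), the neutrophil marker Il1r2 (1.09), the RNase P subunit gene Pop5 (-2.40) and Oasl1 (-1.27), all at adjusted p = 0.162. Pop5 was also lower in untreated replicate 3 than in replicate 2 in each class (-1.83, -1.97 and -1.34), as the set of 30 genes was. Pdcd5 was lower in the same step too (-0.87, -1.12 and -1.2). Over all cells these were Rbm3 (1.21), Rrm2 (0.79), Swt1 (-0.98) and the lysyl hydroxylase gene Plod2 (-1.06) at adjusted p = 0.22. For each of these genes the 3 libraries of the 2 groups did not overlap.

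The comparison of FOLFOX+probiotics with untreated tumours asks what both treatments did together. In Xist-negative cells Nr4a3 rose by 2.26 log2 units (SE 0.35, n = 3 against 3, edgeR adjusted p = 0.0225), Homer1 by 1.59 (SE 0.21, adjusted p = 0.0225), Trim69 by 1.47, the kinase gene Pak1 by 1.26 and the elongation factor gene Ell2 by 1.15. Apoe, a lipoprotein gene and marker of mononuclear phagocytes, fell by 2.14 (SE 0.39, adjusted p = 0.0287). Pop5, Nol7, Mrps15 and Zcrb1 fell by 2.04, 2.01, 1.84 and 1.72, and all 4 had been over 1 log2 unit lower in untreated replicate 3 than in replicate 2. Libraries did not overlap for any of these genes, as the naming rule required. In mononuclear phagocyte-like cells Astl rose by 2.39, Plekhg2 by 2.32 (SE 0.35, adjusted p = 0.00898) and Chil3, a chitinase-like gene of alternatively activated macrophages, by 2.17. Trir fell by 1.92 and Gadd45gip1 fell by 1.84, both in that same step between untreated libraries, and the G protein gene Gng11 fell by 1.83.

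Of the genes tested in Xist-negative cells 517 rose and 358 fell, or 1022 and 114 without scaling factors, and in mononuclear phagocyte-like cells 538 rose and 290 fell, or 549 and 107. DESeq2 called 2398 and 1774. With the library term all 875 and all 828 genes kept their direction, with median ratios of log2 fold changes of 0.921 and 0.885. Their selection on the same libraries favours a kept direction. In Xist-negative cells 0 genes were called by edgeR without untreated replicate 2 or FOLFOX+probiotics replicate 1 or 2, 481 without untreated replicate 3, 316 without FOLFOX+probiotics replicate 3 and 7061 without untreated replicate 1. In mononuclear phagocyte-like cells 204 genes were called without untreated replicate 2, 453 without untreated replicate 3, 202, 192 and 456 without FOLFOX+probiotics replicates 1, 2 and 3, and 5654 without untreated replicate 1. When the clusters that did not pass the naming rule were left out, 0 genes were called in Xist-negative cells (edgeR, 4153 with an unadjusted p under 0.05). A fit of only the 6 libraries compared called 1 and 301.

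Type I interferon genes were lower than in untreated tumours in every class. In T cell-like cells 20 of 21 lay below 0 with a median of -1.36 and all 3 libraries below the untreated ones (camera adjusted p = 3.28e-12, and adjusted p = 0.59 with an estimated correlation). Oasl1, an oligoadenylate synthetase-like gene, fell by 1.60 (SE 0.23, edgeR adjusted p = 0.04) and was the 1 member called, and 19 passed adjusted over the list alone. Mononuclear phagocyte-like cells had 20 of 21 below 0, a median of -1.08 and 2 libraries below all untreated ones (adjusted p = 7.2e-07, and adjusted p = 0.918 with an estimated correlation). There 4 members fell past the threshold, Rtp4 (-1.53), Oas2 (-1.26), Irf7 (-1.53) and Oas1a (-1.25), and 16 passed adjusted over the list alone. With the library term the median was -0.59 in T cell-like and -0.39 in mononuclear phagocyte-like cells. In Xist-negative cells the median was -0.84 with 20 of 21 below 0, 0 called, 9 adjusted over the list alone and 2 libraries below all untreated ones (adjusted p = 0.00056, and adjusted p = 0.776 with an estimated correlation), and the library term gave a median of 0.00. Untreated replicate 1 had the lowest untreated value of this list in each class.

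Antigen presentation and macrophage genes were also lower in Xist-negative cells of FOLFOX+probiotics tumours than in untreated ones. MHC class II genes had 11 of 12 below 0, a median of -0.92 and all 3 libraries below the untreated ones (camera adjusted p = 0.00107, and adjusted p = 0.776 with an estimated correlation). H2-Ab1 (-1.65) and H2-Oa (-1.17) were called and 7 passed adjusted over the list alone, and the library term gave a median of -1.01. Markers of mononuclear phagocytes had 19 of 24 below 0, a median of -0.86 and all 3 libraries below the untreated ones (adjusted p = 0.00301, and adjusted p = 0.776 with an estimated correlation). Of these 5 were called, such as Ms4a7 (-1.95) and C1qc (-1.52), 11 were lower and 1 higher adjusted over the list alone, and the library term gave a median of -0.63. RNA carried from phagocytes was not separated from a change within Xist-negative cells here either.

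Stress response and mitochondrial genes were lower in mononuclear phagocyte-like cells of FOLFOX+probiotics tumours than in untreated ones. Genes of the unfolded protein and integrated stress response had 16 of 17 below 0, a median of -0.74 and all 3 libraries below the untreated ones (camera adjusted p = 0.00169, and adjusted p = 0.918 with an estimated correlation). Herpud1 (-0.82) was called and 4 passed adjusted over the list alone, and the library term gave a median of -0.25. Mitochondrially encoded genes had 13 of 13 below 0, a median of -0.54 and all 3 libraries below the untreated ones (adjusted p = 0.00142, and adjusted p = 0.918 with an estimated correlation). The subunit genes mt-Nd3 (-1.34) and mt-Atp8 (-1.24) were called, both again adjusted over the list alone, and the library term gave a median of -0.23. Oxidative phosphorylation genes had a median of -0.39 with 15 of 19 below 0 and 1 library below all untreated ones (adjusted p = 0.0429, and adjusted p = 0.918 with an estimated correlation). Of these Ndufa4 (-1.28) and Cyc1 (-1.54) were called and 7 passed adjusted over the list alone, adjusted p = 0.131 without the set of 30 genes, which holds Cyc1 and Cox5a, and the library term gave a median of 0.08. The call also ended without untreated replicate 2 (adjusted p = 0.13) or FOLFOX+probiotics replicate 1 (adjusted p = 0.101). Without scaling factors the median of the list was -0.22 with 13 of 19 below 0.

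Over all cells Homer1 rose by 1.41 (SE 0.21, n = 3 against 3, edgeR adjusted p = 0.0391), Trim69 by 1.41 and the matrix gene Ltbp1 by 0.93. The interferon-inducible Ifi27l2a fell by 1.79, Pdcd5 fell by 1.69 and Lst1 fell by 1.36. Each had non-overlapping libraries, as the naming rule required. Pdcd5 was also lower in untreated replicate 3 than in replicate 2 in each class tested (-0.87, -1.12 and -1.2). Over all cells 261 genes rose and 96 fell, or 718 and 31 without scaling factors, and DESeq2 called 2306. With the library term 357 of the 357 genes kept their direction, with a median ratio of log2 fold changes of 0.94. A kept direction is again favoured by selection on the same libraries. The count of called genes was 0, 280, 7498, 0, 1 and 45 without untreated replicates 2, 3 and 1 and FOLFOX+probiotics replicates 1, 2 and 3, and 3 with only the 6 libraries compared. In T cell-like cells 4 genes were called, Oasl1, Trim69 (2.35), Pde4c (4.14) and Gm4841 (-2.20), of which the last 3 lie outside the naming rule and were chosen after their values were seen. The T cell-like count was 4647 without untreated replicate 1, 57 without untreated replicate 3, 2 without FOLFOX+probiotics replicate 3 and 0 without any 1 of the other 3 libraries or with only the 6 libraries compared, DESeq2 called 441 and 2437 genes had an unadjusted p under 0.05. Among classes, mural cells, which wrap vessels, made up 0.0826% ± 0.0431 of untreated and 0.243% ± 0.0728 of FOLFOX+probiotics cells and were not called (log2 difference 1.55, SE 0.45, adjusted p = 0.064, all 3 libraries higher, exact permutation p = 0.1). No class share passed. The immune share differed by less than the spread of replicates (exact permutation p = 0.4), and so did the log2 ratio of CD8 T-like to regulatory T-like cells, 1.60 ± 0.72 and 2.29 ± 0.87 (exact permutation p = 0.4). At a higher clustering resolution, chosen for the ratio after the data were seen, it was 1.05 ± 0.41 in untreated, 2.45 ± 0.74 in FOLFOX and 2.68 ± 0.73 in FOLFOX+probiotics tumours (exact permutation p = 0.1 for both treated groups against untreated, the smallest possible). Other alternatives chosen then gave smaller differences of FOLFOX and FOLFOX+probiotics from untreated. They were 0.82 and 0.43 from marker UMIs (exact permutation p = 0.5 and 0.7). With at least 2000 UMIs per cell they were 0.77 and 0.77 (exact permutation p = 0.4 and 0.3).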

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

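The fixed rules for a closer look had nothing to test here. Groups of 3 are not tested for distant samples, and the design has no interaction and no data outside the comparisons. 3 patterns are weighed because comparisons above rest on them. The tests of the first 2 patterns and the tests of the interferon list against the second library difference and against the level of phagocyte markers were chosen after the result was seen, and the other tests were not.

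Untreated replicates 2 and 3 held a smaller share of UMIs in genes over 50 kb than the other 7 libraries, 12.8% and 12.9% against 20.4% to 21.5%. A lower capture or count of intron RNA or nuclei in these 2 libraries is a candidate explanation: among genes spanning under 50 kb, which did not define the pattern, those with over 10 kb of introns lay below those without introns by at least 0.305 log2 units in each class. Another mix of cell types is argued against, since both libraries lay below the other 7 within 3 of 3 classes. The labels give no batch, so what set these libraries apart was not tested beyond this. The pattern splits the untreated group, so no biological explanation was tested.

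The T cell-like share was higher in FOLFOX+probiotics than in FOLFOX tumours, by 1.63 log2 units (SE 0.49, adjusted p = 0.037, higher in 3 of 3 libraries). With 1 doublet rule in every library the difference was 1.702 (SE 0.516, adjusted p = 0.0781), and with at least 2000 UMIs per cell it was 1.446 (SE 0.501, adjusted p = 0.0707). Both corrections end the call. With 1 doublet rule the raw edgeR p went from 0.00924 to 0.00976, and the endothelial class no longer passed ahead of it. With at least 2000 UMIs the raw edgeR p rose to 0.0177. Differences of this size argue against either rule as the sole cause. A lower share of Xist-negative cells alone would leave the ratio of T cell-like to mononuclear phagocyte-like cells unchanged, and its log2 was higher by 1.489 (-1.33 ± 0.94 against -2.82 ± 0.71, exact permutation p = 0.1). An effect of the probiotics on T cells and an uneven yield of T cells among 3 tumours per group both stay open, with 1.14 without FOLFOX+probiotics replicate 2.

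The type I interferon list was lower in FOLFOX+probiotics than in FOLFOX tumours in all 3 classes. RNA of mononuclear phagocytes in other droplets was not decided by their markers, whose median lay above that of the interferon list by at least 0.68 in Xist-negative and T cell-like cells, because the list fell by 0.84 in the phagocytes too. Such RNA in the share the markers give is argued against as the cause in those 2 classes, since relative to phagocytes the interferon genes lay above the markers by at least 3.624 log2 units. A single library is argued against, since the list stayed called without each of the 6 libraries in all 3 classes (18 of 18 calls). The 18 calls are not independent, because the 3 classes come from the same 6 tumours. Gene deviations of these libraries correlated between classes at 0.38 to 0.86 over 3053 genes. The second library difference, which lowers 30 genes in untreated replicate 3 and in the FOLFOX+probiotics libraries, stays open, since the list was higher by at least 0.14 in untreated replicate 3 than in replicate 2 but 1 library excludes nothing, and so do a batch that the labels do not give, an effect of the probiotics, and the loss of every call with an estimated correlation.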

How the results depend on the processing

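Tests with at least 2000 UMIs per cell, 1 doublet rule in every library, clusters that passed the naming rule, the library term, marker UMI ratios and the ratio at a higher clustering resolution were chosen after the result was seen. Of class shares 276 values kept direction and side of the threshold, 9 passed anew, 11 no longer passed and 4 changed sign. Of named genes 625 kept both, 56 passed anew and 302 no longer passed, and of main results 239 stayed within 1.5 times the count, the spread of replicates or their side of the threshold, 149 moved and 3 changed sign. The cause was not tested except where an alternative has fewer libraries or genes.

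The number of class shares called between FOLFOX+probiotics and FOLFOX, 2, was 0 with 1 doublet rule, at least 2000 UMIs or TMM scaling and 1 as shares of immune cells, and between FOLFOX+probiotics and untreated it was 2 with stricter cells or doublets kept. The endothelial difference was 1.255, 1.180 and 1.122 with 1 doublet rule, at least 2000 UMIs and TMM (adjusted p = 0.283, 0.0707 and 0.147; higher in 3 of 3 libraries), and the T cell-like difference 1.702, 1.446 and 1.320 (adjusted p = 0.0781, 0.0707 and 0.147). The mononuclear phagocyte-like share changed sign to 0.0645 as a share of immune cells (FOLFOX and untreated), and to -0.1233 with TMM, -0.3106 as a share of immune cells and -0.02773 without FOLFOX+probiotics replicate 3 (FOLFOX+probiotics and FOLFOX). The log2 ratio of CD8 T-like to regulatory T-like cells in that comparison changed sign to -0.001521 with at least 2000 UMIs, -0.3951 from UMIs and -0.2105 without FOLFOX+probiotics replicate 2. At a higher clustering resolution it moved to 1.397 for FOLFOX and 1.631 for FOLFOX+probiotics against untreated (exact permutation p = 0.1 each, the smallest possible).

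Gene counts are given for FOLFOX against untreated, FOLFOX+probiotics against FOLFOX, and FOLFOX+probiotics against untreated. DESeq2 called 3665, 512 and 2398 in Xist-negative, 1087, 180 and 1774 in mononuclear phagocyte-like, 82, 97 and 441 in T cell-like and 2483, 518 and 2306 in all cells. Without a filter the counts were 89 and 1387 (Xist-negative, last 2 comparisons), 1633, 569 and 2499, 252, 183 and 716, and 506 and 790 (all cells, comparisons with untreated). With only 6 libraries they were 0, 173 and 1, then 215, 47 and 301, then 0, 167 and 0, then 3, 175 and 3. No scaling gave 0 and 0 in T cell-like and 845 and 749 in all cells against untreated. The library term, with untreated replicate 1 as the lone library of its group, gave 6 and 0 in Xist-negative, 8 and 54 in mononuclear phagocyte-like, 2 in T cell-like (last comparison) and 0 and 0 in all cells. Clusters that passed the naming rule gave 0 and 0 in Xist-negative cells. T cell-like counts against untreated were 0 and 0 with stricter cells, 1 doublet rule or at least 2000 UMIs, and 2 and 13 with doublets kept.

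List calls were 0 in all 12 tests with an estimated correlation. With the library term they were 17 in mononuclear phagocyte-like and 12 in all cells for FOLFOX, and 4, 15, 5 and 5 in Xist-negative, mononuclear phagocyte-like, T cell-like and all cells for FOLFOX+probiotics against untreated.

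Leaving out 1 library gave these lowest and highest values, in the order of comparisons above. Class shares called were 0 to 3, 0 to 3 and 0 to 1, the mononuclear phagocyte-like difference between FOLFOX+probiotics and FOLFOX -0.02773 to 0.4025, the endothelial one 1.158 to 1.626 and the T cell-like one 1.138 to 2.206. Genes called were 1 to 7178, 0 to 112 and 0 to 7061 in Xist-negative, 61 to 5467, 0 to 27 and 192 to 5654 in mononuclear phagocyte-like, 0 to 3961, 0 to 24 and 0 to 4647 in T cell-like and 3 to 6727, 0 to 29 and 0 to 7498 in all cells. Lists called were 11 to 20, 8 to 13 and 7 to 17, then 4 to 11, 6 to 10 and 5 to 11, then 10 to 22, 9 to 16 and 8 to 17, then 13 to 28, 14 to 26 and 4 to 13. The immune share difference was -21.89 to -10.67, 6.683 to 14.15 and -11.88 to -0.6585 points, and the CD8 T-like ratio 0.108 to 0.8077, -0.2105 to 0.6164 and 0.2018 to 1.092.

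Depth limits the classes with few cells: 21 endothelial cells in the smallest library lay under the 50 planned for a gene test, and T cell-like tests rest on 247 to 1721 cells.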

Other observations

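The counts over other splits of the samples in this part were planned, and of the tests only those with the library term were chosen after the result was seen.

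Each comparison of 3 with 3 libraries has 10 splits, which are too few for a share under 0.05. For FOLFOX and untreated tumours, edgeR called 1818 genes in Xist-negative cells and at most 384 in another split (1 split as large, the real one included), 420 and 303 in mononuclear phagocyte-like cells (1), 1 and 935 in T cell-like cells (2), and 242 and 400 over all cells (2). The high other split puts FOLFOX replicate 1 with untreated replicates 2 and 3, which points to a structure of the samples. Lists called were 13 and at most 16 (5 splits), 8 and 17 (10), 13 and 16 (4), and 20 and 19 (1) in the same order of classes.

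For FOLFOX+probiotics and FOLFOX tumours edgeR called 0 genes in every class and 0 in every other split (10 splits each), where 2833, 1633, 806 and 2582 genes had an unadjusted p under 0.05 and DESeq2 called 512, 180, 97 and 518. Lists called were 12 and at most 21 (7 splits), 7 and 13 (9), 14 and 17 (4), and 27 and 23 (1). For FOLFOX+probiotics and untreated tumours the genes were 875 and at most 3, 828 and 0, 4 and 0, and 357 and 0 (1 split each), and the lists were 10 and 16 (6), 5 and 17 (10), 14 and 17 (4), and 9 and 18 (9).

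Platelet markers were higher in mononuclear phagocyte-like cells of both treated groups than in untreated tumours, with 4 of 4 above 0 in each comparison. The median was 1.64 in FOLFOX (camera adjusted p = 0.0143, and adjusted p = 0.843 with an estimated correlation) and 1.59 in FOLFOX+probiotics tumours (adjusted p = 0.00878, and adjusted p = 0.654 with an estimated correlation), and all 3 treated libraries lay above the untreated ones. Tubb1 (2.01 and 2.07), a tubulin of platelets, and the integrin gene Itga2b (1.43 and 1.22) were called in both. The adjusted p was 0.129 and 0.11 without untreated replicate 1, and the library term, which compares with that library alone, gave medians of 1.56 and 1.49. Both comparisons share the untreated libraries.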
